A study of Mus musculus with 6 samples.

How the data were processed

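Total RNA was measured in 6 libraries of 4T1 cells, an established mouse mammary carcinoma line, in 3 groups of 2: wild type and 2 clones in which Mki67 was knocked out. Per the labels' protocols, RNA was extracted with Trizol, depleted of ribosomal RNA and made into stranded total RNA libraries, which were sequenced on a HiSeq 2500. Per the submitters' processing notes, reads were checked with FastQC and aligned with STAR 2.6.0c to GRCm38. The deposited values are counts of reads per gene, 1 table per library, each with 54146 Ensembl genes and separate columns for unstranded, forward and reverse counting. The authors' counts are not normalized. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The libraries of each group differed by more than sampling noise (chi-square per degree of freedom 82.2 in WT, 19.4 in clone 1 and 26.6 in clone 2), so none was treated as a copy of another library. This does not separate cultures from repeat preparations.

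Column 4, the reverse-strand count, was used in each table because it held 92.3% to 95.7% of the stranded gene reads. Rows that name no gene were left out of library sizes and tests. Of all reads, 8.49% to 14.0% were unmapped, 24.7% to 29.3% mapped to several places, 9.21% to 13.5% lay outside genes, 1.90% to 2.74% were ambiguous, and 43.2% to 53.1% were assigned to a gene. The 10 most abundant genes held 28.4% and 24.8% of the gene reads in WT, 20.5% and 21.2% in clone 1, and 17.7% and 15.0% in clone 2. A floor of 3 counts corresponded to 0.132 to 0.288 CPM. Symbols and coordinates came from GENCODE mouse release 21 on GRCm38, which matched 54079 of the IDs and left 67 unmatched.

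Tests were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with enough reads were kept with filterByExpr, which left 13755 of the 26172 genes with at least 1 read and removed at most 0.107% of the reads of a library. Library sizes were scaled by TMM, and CPM were computed with the scaled library sizes. A quasi-likelihood model with 1 term per group and robust dispersion was fitted to all 6 libraries, which leaves 3 residual degrees of freedom. The common biological coefficient of variation was 10.3%. The contrasts were clone 1 against WT, clone 2 against WT, the mean of both clones against WT, and clone 2 against clone 1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. For genes with no read in a group, a bound was computed from a floor of 3 counts over the group or groups named, and for 1 to 3 reads a ratio with an exact 95% interval. Bounds, floors and intervals cover counting error only.

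The 31 gene lists, the comparisons, the rule for named genes and most of the alternatives were fixed before the data were examined. Of 1152 list members 1148 matched a gene, and 42 genes were in more than 1 list. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. No list's median differed when members with no read in either clone were set at their bound. Counts adjusted over the list alone used the p-values of the list's members only. Named genes were 22 genes fixed in advance, then the 10 largest and 10 smallest changes among genes called in both clones in the same direction with an average log2 CPM of at least 3 and an ordinary symbol. They also included, for each clone and direction, the 4 largest changes called in that clone, not in the other, and called between the clones. From each list, up to 4 members with the smallest adjusted p among those called in both clones were named, or with fewer than 2 such members the member with the smallest adjusted p in each clone. Other list members, named because few moved against their list, and the other genes outside this rule were chosen after their values were seen. The result of 1 gene that this rule names is not reported here.

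The test was run on simulated counts with 200 changed genes. Over 10 draws of the mean contrast on 13755 genes, a median of 9.54% of the calls were false (3.33% to 12.9%) and 73.5% of the changed genes were recovered. In a single draw on 13366 genes the mean contrast recovered 49.25% of 1.5-fold, 82.09% of 2-fold and 93.94% of 4-fold changes, with 18 false among 168 calls. For clone 1 the shares were 40.3%, 76.12% and 93.94%, with 15 false among 155 calls, and for clone 2 they were 26.87%, 76.12% and 90.91%, with 19 false among 148.

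Alternatives were DESeq2 1.42.0 size factors and its Wald test, upper-quartile scaling, no count filter, a filter of 1 CPM in 2 libraries, limma-voom, the legacy quasi-likelihood fit, a minimum change of 1.5-fold, unstranded counts, only the groups compared, a replicate block, and each library left out in turn, where a lone library is assumed to vary like the other groups. A fit with the median shift of each chromosome removed, and a fit without mitochondrially encoded genes and genes that collect ribosomal RNA reads, were added after the data were seen, as was a split of the WT libraries between the clones. Reads of MHC class I genes, histones, ribosomal proteins and Ftl1 can be shared with near-identical copies, so their values are uncertain.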

Results

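Gene expression was measured in 4T1 cells, a mouse mammary carcinoma line from the BALB/c strain, by strand-specific sequencing of total RNA from which ribosomal RNA had been depleted. Wild-type (WT) cells were compared with 2 clones in which Mki67, the gene of the proliferation marker Ki-67, had been knocked out. Each of the 3 groups had 2 libraries. The reads assigned to genes came to 10428970 and 16852152 in the WT libraries, 22597596 and 22658499 in clone 1, and 17103941 and 22275937 in clone 2. Of the genes counted, 13755 had enough reads to be tested. Expression levels are given as CPM, gene counts scaled by the size of the library, as the mean ± SD of n = 2 libraries, and fold changes are log2 values fitted by edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p-values. Across genes, the log2 CPM of the replicates correlated with r = 0.985 in WT, 0.995 in clone 1 and 0.993 in clone 2, and WT correlated with the clones at 0.913 to 0.925. The clones correlated with each other at 0.978 to 0.982. These correlations are over genes, which are not independent replicates. In a multidimensional scaling of the 6 libraries, the first axis held 77.5% of the variance and set WT apart from both clones, and the second axis held 13.2% and set the clones apart from each other.

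The targeted gene was read in every library. Mki67 (ENSMUSG00000031004; GRCm38 chromosome 7, 135689784 to 135716361, minus strand) had 736 and 647 CPM in the WT libraries, 85.8 and 103 CPM in those of clone 1, and 39.9 and 52.8 CPM in those of clone 2. Its level fell from 692 ± 63.0 CPM in WT to 94.2 ± 11.8 CPM in clone 1 (log2 fold change -2.88, SE 0.154, adjusted p = 1.13e-08) and to 46.3 ± 9.07 CPM in clone 2 (-3.90, SE 0.161, adjusted p = 1.52e-09). Clone 2 lay below clone 1 (-1.02, adjusted p = 0.000503). Gene-level counts do not show which part of the gene was altered.

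**Figure D1:**
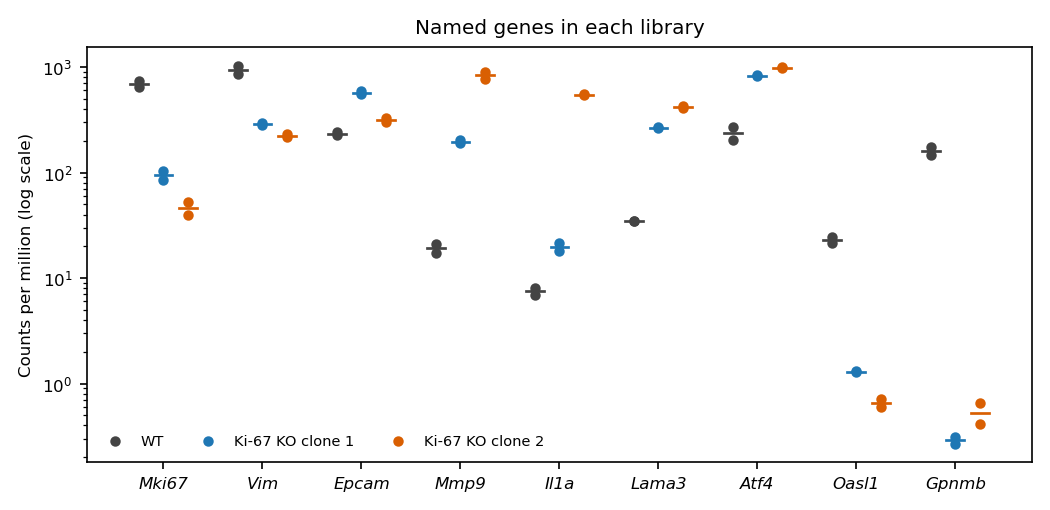
CPM (log scale) of 9 genes in each of the 6 libraries. Points are single libraries and bars the mean of the 2 libraries of WT (black), Ki-67 knockout clone 1 (blue) and clone 2 (orange). Mki67 lay at 692 CPM in WT against 94.2 and 46.3 CPM in the clones, and Il1a at 7.47 CPM in WT against 19.9 and 546 CPM.

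The genotype comparison asked which genes differed between Ki-67 knockout and WT cells, as the mean of both clones against WT. Its p-values measure the spread between libraries of the same line, not between independent lines. Effects of losing Ki-67 can therefore not be told apart from differences between cell lines. Mmp9, the gelatinase B that degrades basement membrane collagen, rose from 19.2 ± 2.59 CPM in WT to 196 ± 8.04 in clone 1 and 841 ± 90.0 in clone 2 (log2 fold change of the mean 4.40, SE 0.140, adjusted p = 5.7e-11). Ap1m2, a subunit of the epithelial form of the AP-1 clathrin adaptor, rose from 0.227 ± 0.237 CPM to 48.1 ± 0.329 and 53.9 ± 3.58 CPM (8.04, SE 0.286, adjusted p = 1.28e-10). At the lower end, Hexa, which encodes the alpha subunit of the lysosomal enzyme hexosaminidase A, had 79.9 ± 5.16 CPM in WT and no read in any of the knockout libraries, which makes it at least 2240-fold lower when 3 counts over both clones are taken as the floor.

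The 10 largest increases shared by both clones also included the matrix glycoprotein gene Tnc (3.93), the G-protein signalling regulator Rgs16 (3.82), the cytokine gene Il1a (3.81), the adhesion molecule L1cam (3.68), the stromelysin Mmp10 (3.68), the Notch ligand Dll4 (3.30), Tmem51 (3.29) and the metalloprotease Adam12 (3.28). Adjusted p-values of these genes ran from 1.5e-10 for Il1a to 2.3e-07 for Rgs16. Among the 10 largest decreases, Mal2, a membrane protein of transcytosis in polarised epithelia, had 66.0 ± 9.94 CPM in WT and 1 read in each clone, a ratio of 2731 with an exact 95% interval of 754.8 to 22570. Vldlr, the receptor for very low density lipoprotein, had 37.2 ± 3.4 CPM in WT and 1 read over both clones, a ratio of 3117 with an interval of 558.2 to 123200. The glycoprotein gene Gpnmb fell from 162 ± 19.4 CPM to 0.289 ± 0.0274 and 0.530 ± 0.166 CPM (-8.64, adjusted p = 1.89e-13), and Lcp1, the actin-bundling protein L-plastin, from 155 ± 5.12 CPM to 0.266 ± 0.122 and 0.793 ± 0.0386 CPM (-8.37, adjusted p = 1.89e-13). The remaining members of this group were the interferon-inducible surface protein gene Ly6e (-7.57), the cilium gene Dzip1 (-7.23), Zfp704 (-6.74), the myelin protein gene Pmp22 (-6.71) and Cd74, the invariant chain of MHC class II (-6.52).

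In this comparison 7673 of 13755 genes were called, 3645 higher and 4028 lower in the clones, and 1005 and 1609 of them changed by more than 2-fold. When the test required a change of more than 1.5-fold, 2870 genes were called, and Nlrc5, Pcna, Mcm2, Top2a, Notch1, Sdhd, Sdhc, Uqcrq, Fkbp4 and Rpl13, and mt-Nd6 in clone 1, lost their call. On simulated counts with 200 changed genes the test gave a median share of false calls of 9.54% over 10 draws against the nominal 5%. That share depends on how many genes change, so it does not carry over to this comparison, where 7673 were called. Nor did the simulation test the scaling of libraries with so many changed genes. Calls near the threshold may still be less certain than their adjusted p-values state.

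Genes induced by interferon were lower in the clones. Of the 35 tested members of this list, 34 fell and none rose, with a median log2 fold change of -2.67, and 32 fell in both clones. Oasl1, an antiviral protein of the oligoadenylate synthetase family, fell from 22.97 ± 2.08 CPM to 1.29 ± 0.0181 in clone 1 and 0.655 ± 0.0723 in clone 2. Gbp2, a guanylate-binding GTPase, fell from 26.2 ± 1.73 CPM to 1.40 ± 0.0118 and 1.02 ± 0.447, and Oasl2 (-4.99) and Ifit2 (-2.95), both antiviral effectors, fell as well. The member that was not called was Ifitm3 (-0.15, adjusted p = 0.649). The camera test gave an adjusted p = 6.76e-26 for the list, and adjusted p = 0.305 with an estimated correlation. The counts adjusted over the list alone were identical.

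Antigen presentation by MHC class I was also lower as a group, with 18 of 28 members lower, 2 higher and a median of -0.52. Psmb8, a subunit of the immunoproteasome, fell from 34.8 ± 9.94 CPM to 0.780 ± 0.168 and 0.973 ± 0.211 CPM. The peptide transporter genes Tap1 (-1.58) and Tap2 (-2.21), the transcription factor Irf1 (-1.28) and the proteasome activator Psme1 (-1.16) fell in both clones. Nlrc5, a transactivator of MHC class I genes, fell by 0.74 (adjusted p = 0.00271), a call that was lost without WT replicate 2 (adjusted p = 0.106). The classical class I genes themselves were not called. H2-K1 had 169.4 ± 39.3, 180 ± 4.97 and 162 ± 0.877 CPM in WT, clone 1 and clone 2 (adjusted p = 0.953), and H2-D1 had 278 ± 13.3, 280 ± 5.49 and 279 ± 21.8 CPM (adjusted p = 0.979). B2m, their light chain, had 509 ± 185, 342 ± 27.5 and 396 ± 131 CPM (adjusted p = 0.255). The members that rose were Psme3 and Pdia3. The list's camera adjusted p was 0.000566, with adjusted p = 0.575 with an estimated correlation and identical counts adjusted over the list alone. The values of H2-K1 and B2m depended on the WT library kept. H2-K1 was called at 0.27 without WT replicate 2 (adjusted p = 0.0465) and lay at -0.20 without WT replicate 1 (adjusted p = 0.113), and B2m lay at -0.80 (adjusted p = 0.0505) and -0.03 (adjusted p = 0.936) and was called at -0.65 without clone 2 replicate 1 (adjusted p = 0.0412). With the median shift of each chromosome removed, H2-K1 (-0.43, adjusted p = 0.00866) and H2-D1 (-0.43, adjusted p = 0.00177) were called as lower and the list's median was -0.96. That setting was chosen after the data were seen.

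Markers of immune cells were measured beside these groups. Of 24 listed markers 4 had enough reads to be tested. Cd74 fell from 26.6 ± 8.36 CPM to 0.466 ± 0.214 and 0.175 ± 0.00282, and the lysosomal protein gene Cd68 from 12.9 ± 3.68 to 2.74 ± 0.182 and 2.82 ± 0.930. Csf1r, the receptor for macrophage colony-stimulating factor, rose from 1.14 ± 0.221 to 2.22 ± 0.221 and 3.12 ± 0.166 CPM. Cd14, a co-receptor for lipopolysaccharide, had 9.23 ± 2.31 CPM in WT, 7.48 ± 0.672 in clone 1 (adjusted p = 0.166) and 20.9 ± 2.03 in clone 2 (adjusted p = 0.000124), and the mean of both clones was higher by 0.42 (adjusted p = 0.04). Ptprc, the pan-leukocyte marker CD45, averaged 0, 0.0445 and 0.102 CPM. The list's median was -0.89 (camera adjusted p = 0.0379, adjusted p = 0.366 with an estimated correlation), a call that was lost on leaving out any 1 of the knockout libraries (adjusted p = 0.168 and 0.156 without clone 1 replicates 1 and 2, and 0.0719 and 0.129 without clone 2 replicates 1 and 2), with a filter of 1 CPM (0.0532) and without a filter on low counts (0.569, with a median of -0.106). It was called in clone 1 (median -1.27, camera adjusted p = 0.0281, and adjusted p = 0.42 with an estimated correlation) and not in clone 2 (median -0.52, camera adjusted p = 0.205). For the mean of both clones all 4 members passed the test, and the counts adjusted over the list alone were identical. Of the fibroblast and endothelial markers 2 of 24 were tested. Pdgfra, a growth factor receptor, fell from 39.3 ± 0.143 to 14.4 ± 0.108 and 14.4 ± 0.0960 CPM, and Egfl7 was not called, with identical counts adjusted over the list alone (camera adjusted p = 0.144, and 0.592 with an estimated correlation). Of 6 tested mammary luminal, basal and milk genes, the growth factor gene Areg (3.26) and the basal keratin Krt14 (0.64) rose, and the casein gene Csn3 (-3.78) and the oestrogen receptor gene Esr1 (-1.13) fell (camera adjusted p = 0.619, and 0.691 with an estimated correlation). Their median was -0.52, or -0.209 with a filter of 1 CPM, while camera gave the direction as up, and adjusted over the list alone 2 rose and 3 fell.

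Detoxification genes were lower in the clones. Of 33 tested genes of xenobiotic metabolism and transport, 22 fell and 5 rose, with a median of -1.03, and adjusted over the list alone 23 fell. Mgst1, a microsomal glutathione transferase, fell from 74.5 ± 8.60 CPM to 0.955 ± 0.333 and 4.33 ± 0.0432. Gsta4, a glutathione transferase that acts on lipid peroxidation products, fell from 153 ± 0.717 to 7.98 ± 1.25 and 15.7 ± 1.27 CPM, and the epoxide hydrolase gene Ephx1 (-3.71) and the aldehyde dehydrogenase gene Aldh3a1 (-4.15) fell in both clones. The members that rose were Sult2b1, Mgst3, Abcb1b, Abcc1 and Abcc4. The list's camera adjusted p was 2.8e-10, and adjusted p = 0.305 with an estimated correlation. Its median moved to -1.66 without clone 1 replicate 1 and to -1.64 with a filter of 1 CPM.

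Targets of the antioxidant transcription factor NRF2 shared 1 tested member, Abcc1, with that group. Of 27 tested, 16 fell and 5 rose, with identical counts adjusted over the list alone and a median of -0.52. Nqo1, a quinone reductase, fell from 28.0 ± 5.25 CPM to 9.22 ± 1.14 and 8.49 ± 1.07 (-1.66, adjusted p = 5.06e-07), and the ferritin light chain gene Ftl1 from 618 ± 69.1 to 144 ± 2.67 and 145 ± 6.33 CPM. Blvrb, a biliverdin reductase, fell by 2.05. The aldo-keto reductase gene Akr1c13 had 5.54 ± 0.437 CPM in WT, no read in clone 1 and 4 reads in clone 2. Osgin1, an oxidative stress response gene, moved the other way, from 5.90 ± 1.09 to 22.7 ± 1.20 and 34.9 ± 0.290 CPM, and Gsr, Abcc1, Akr1b8 and Slc6a9 rose too. Camera gave the list an adjusted p = 0.00588, and adjusted p = 0.512 with an estimated correlation.

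Genes of ribosome production were higher in the clones. Of 48 tested genes of ribosome biogenesis and the nucleolus, 36 rose and 1, Taf1b, fell, with a median of 0.68, and 32 rose in both clones. Adjusted over the list alone, 37 rose and 2 fell. Nop56, a core protein of box C/D snoRNPs, rose from 167.8 ± 8.54 CPM to 557 ± 26.4 and 621 ± 16.2. Nat10, an RNA acetyltransferase, rose from 56.0 ± 3.66 to 145 ± 2.12 and 175 ± 6.66 CPM, and Rrp9 (1.39) and Heatr1 (1.34), both needed for pre-rRNA processing, rose in both clones. The camera adjusted p was 2.3e-09, and adjusted p = 0.305 with an estimated correlation.

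Of 58 tested cytoplasmic ribosomal protein genes, 20 rose and 5 fell, with 19 and 5 when adjusted over the list alone, and the median was 0.24. Rps2 rose from 9.25 ± 1.14 CPM to 21.7 ± 0.336 and 18.3 ± 2.32, and Rpl13 (0.77), Rps18 (0.90) and Rpl10a (0.92) rose in both clones. Rpl22, Rpl23, Rplp1, Rps4x and Rps24 fell. The camera adjusted p of 0.0379 became 0.0528 without clone 2 replicate 1 and 0.0515 with a filter of 1 CPM, and was adjusted p = 0.592 with an estimated correlation. The list was called in clone 1 (median 0.24, camera adjusted p = 0.0452, and adjusted p = 0.575 with an estimated correlation) and not in clone 2 (median 0.255, camera adjusted p = 0.0732). With the median shift of each chromosome removed, the changes of Rps2 (0.68), Rps18 (0.47), Rpl10a (0.48) and Rpl13 (0.40) were smaller and still called.

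Of 50 genes of S phase and DNA replication, 19 rose and 10 fell, with identical counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.135, and 0.691 with an estimated correlation). Ccne1, the G1/S cyclin E1, rose from 6.95 ± 0.199 CPM to 15.2 ± 1.60 and 27.8 ± 2.31. Uhrf1, which couples DNA methylation to replication, rose by 1.09, the uracil-DNA glycosylase gene Ung by 1.33 and the origin licensing factor gene Cdt1 by 0.97. The replication genes Mcm2 (202 ± 0.0802 CPM in WT, 277 ± 17.1 and 351 ± 24.8 in the clones, adjusted p = 0.000122) and Pcna (147 ± 0.0536, 225 ± 29.5 and 192 ± 23.7 CPM, adjusted p = 0.00195) rose. Without a filter on low counts the S phase list was called (adjusted p = 0.0123). The call of Pcna was lost with chromosome shifts removed (adjusted p = 0.228), and the changes of Mcm2 (0.35), Uhrf1 (0.65) and Cdt1 (0.60) were smaller there.

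Of 50 genes of G2 and mitosis, 10 rose and 21 fell, or 22 when adjusted over the list alone (camera adjusted p = 0.466, and 0.856 with an estimated correlation). Top2a, the topoisomerase that untangles chromosomes, fell from 1198 ± 31.8 CPM to 750 ± 62.6 and 670 ± 74.9 (-0.76, adjusted p = 3e-05). The kinetochore gene Nuf2 (-1.06), the spindle genes Hmmr (-1.11) and Dlgap5 (-0.95) and the kinase gene Aurkb (-0.80) fell in both clones. Ccnb1, the mitotic cyclin B1, was not called, with 43.5 ± 5.68, 45.1 ± 4.35 and 50.1 ± 2.50 CPM (adjusted p = 0.354). Replication-dependent histone genes rose as a group, 19 of 26 with none lower and a median of 0.83. Hist1h4i rose from 49.6 ± 8.40 CPM to 140 ± 10.97 and 124 ± 19.9, and Hist1h2ac (1.15), Hist1h2ae (1.14) and Hist1h3c (0.86) rose in both clones. The camera adjusted p of the histones was 0.000123, with identical counts adjusted over the list alone and adjusted p = 0.592 with an estimated correlation.

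Of 25 p53 targets and cell cycle inhibitors, 9 rose and 11 fell, or 12 when adjusted over the list alone (camera adjusted p = 0.974, and 0.973 with an estimated correlation), and its median of -0.25 and the direction given by camera differed in sign. The median was -0.12 without WT replicate 2 and -0.081 with chromosome shifts removed. Cdkn1a, which encodes the kinase inhibitor p21, rose from 7.76 ± 1.71 CPM to 24.1 ± 1.25 and 24.9 ± 0.812 (1.68, adjusted p = 7.21e-07). The p53 gene Trp53 rose from 27.5 ± 0.682 to 59.8 ± 3.82 and 71.1 ± 6.25 CPM, and the list members Aen (1.29) and Plk2 (1.18) rose as well. RNA levels do not show whether p53 protein was present or active, so these rises are not tied to it. Trp53inp1, a stress-induced p53 partner, fell from 53.1 ± 9.22 to 7.59 ± 0.366 and 3.04 ± 0.203 CPM.

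Of 40 tested epithelial genes, 19 rose and 6 fell, with identical counts adjusted over the list alone and a median of 0.28 (camera adjusted p = 0.00214, and adjusted p = 0.366 with an estimated correlation). The laminin subunit genes Lama3, from 34.6 ± 0.386 CPM to 267 ± 7.71 and 420 ± 14.57, and Lamb3, from 138 ± 25 to 302 ± 10.8 and 563 ± 8.75, rose together with the integrin gene Itga6 (1.33) and the transcription factor Ovol1 (1.85). Epcam, an epithelial adhesion molecule, rose from 234 ± 7.67 to 573 ± 28.9 and 316 ± 16.3 CPM (0.86, adjusted p = 7.48e-06), and its change was 0.43 with chromosome shifts removed. Cdh1, the gene of E-cadherin, had 388 ± 0.122 CPM in WT, 451 ± 4.10 in clone 1 (0.22, adjusted p = 0.115) and 305 ± 28.1 in clone 2, where it fell (-0.35, adjusted p = 0.018), and was not called for the mean of both clones (-0.06, adjusted p = 0.601). With chromosome shifts removed it was called at -0.43 (adjusted p = 0.00191). Vim, the mesenchymal intermediate filament vimentin, fell from 939 ± 123 CPM to 291 ± 8.96 and 224 ± 12.1 (-1.88, adjusted p = 5.5e-09).

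Of 21 tested mesenchymal genes 11 rose and 9 fell, with identical counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.3, and 0.691 with an estimated correlation). Its members included Mmp9, Tnc and Vim, and Sparc, a matrix glycoprotein that fell from 154 ± 8.45 CPM to 21.2 ± 1.62 and 49.8 ± 2.84. Cdh2, Zeb1, Snai2, Aldh1a1 and Aldh1a3 had 0 to 2 reads in each library and were not tested. Among extracellular matrix and basement membrane genes, 17 of 33 rose and 9 fell, with a median of 0.73 and identical counts adjusted over the list alone. Thbs1, the matrix protein thrombospondin 1, fell from 863 ± 184 CPM to 275 ± 14.52 and 222 ± 3.83. The matrix list had a camera adjusted p of 0.0379, which became 0.327 without WT replicate 1, 0.0792 without a filter on low counts and 0.0559 with a filter of 1 CPM, and adjusted p = 0.691 with an estimated correlation. It was called in clone 2 (median 0.71, camera adjusted p = 0.0138, and adjusted p = 0.623 with an estimated correlation) and not in clone 1 (median 0.59, camera adjusted p = 0.0676).

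Immediate early genes, which respond to growth factors and stress, rose as a group. Of 31 tested, 22 rose and 3 fell, with a median of 0.84 and identical counts adjusted over the list alone. Ier3 rose from 45.6 ± 0.891 CPM to 227 ± 6.02 and 359 ± 39.3, the AP-1 component Fosl1 from 13.01 ± 0.970 to 62.1 ± 3.48 and 89.0 ± 9.56, and Ier2 (2.19) and the phosphatase gene Dusp5 (2.29) rose in both clones. Fosl2, Jun and Klf2 fell. The camera adjusted p was 1.99e-08, and adjusted p = 0.24 with an estimated correlation, the lowest of the 31 lists.

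Of 34 genes of the unfolded protein and integrated stress response, 17 rose and 6 fell, or 18 and 6 when adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.0229, and adjusted p = 0.366 with an estimated correlation). The list was called in clone 2, with 19 higher, 6 lower and a median of 0.349 (camera adjusted p = 0.00154, and adjusted p = 0.217 with an estimated correlation), and not in clone 1, with 14 higher, 8 lower, a median of 0.030 and a mean of -0.018 (camera adjusted p = 0.11). Atf4, the central transcription factor of the integrated stress response, rose from 237 ± 45.0 CPM to 831 ± 1.37 and 990 ± 10.9, and its target genes Trib3 (2.05) and Atf3 (1.74) rose in both clones. The members that fell were Hsp90b1, Eif2ak3, Dnajc3, Sel1l, Ddr2 and Vldlr. With chromosome shifts removed the list's median was 0.17. Of 21 heat shock genes 3 rose and 8 fell, with identical counts adjusted over the list alone (camera adjusted p = 0.225, and 0.592 with an estimated correlation). Hspb8 fell from 160 ± 0.840 CPM to 28.6 ± 1.96 and 62.8 ± 8.60, Dnajb4 fell by 1.35 and Hspb1 was at least 60.8-fold lower, with no read in the clones on the strand that was counted and a fitted change of -4.00 with unstranded counts. The chaperone gene Fkbp4 rose by 0.73, and by 0.45 with chromosome shifts removed.

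Of 32 genes of cholesterol and lipid synthesis, 20 rose and 4 fell, or 21 and 5 when adjusted over the list alone, with a median of 0.44 (camera adjusted p = 0.0272, and adjusted p = 0.679 with an estimated correlation). The list was called in clone 2 (median 0.51, camera adjusted p = 0.00991, and adjusted p = 0.623 with an estimated correlation) and not in clone 1 (median 0.36, camera adjusted p = 0.0955). The sterol enzyme genes Msmo1, from 98.5 ± 17.3 CPM to 224 ± 25.7 and 226 ± 14.2, and Cyp51 (1.06) rose. The members that fell were Scd1 (-1.33), Scd2, Srebf1 and Me1. Hypoxia and glycolysis genes were not called as a list, with 9 of 38 higher and 13 lower and identical counts adjusted over the list alone (camera adjusted p = 0.284, and 0.691 with an estimated correlation). Their median was 0.03, while their mean of -0.61 and both tests gave the direction as down. The glycolytic genes Eno2, from 10.97 ± 2.69 CPM to 0.222 ± 0.123 and 0.298 ± 0.00547, and Aldoc (-5.41) fell, as did the mitophagy gene Bnip3 (-2.00). The collagen hydroxylase gene P4ha2 fell from 5.20 ± 0.661 to 0.0666 ± 0.0305 and 0.438 ± 0.131 CPM. Of 45 nuclear-encoded genes of oxidative phosphorylation 2 rose, Uqcrc1 and Cox4i1, and 11 fell, or 10 when adjusted over the list alone (camera adjusted p = 0.622, and 0.856 with an estimated correlation). Ndufb3 (-1.27), Sdhd (-0.74), Sdhc (-0.53) and Uqcrq (-0.52) were among those that fell.

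Of 28 Notch pathway genes 14 rose and 7 fell for the mean of both clones, or 14 and 8 when adjusted over the list alone, with a median of 0.45. The list was called in clone 1, with 12 higher, 5 lower and a median of 0.235 (camera adjusted p = 0.0104, and adjusted p = 0.42 with an estimated correlation), and not in clone 2, with 12 higher, 9 lower and a median of 0.073 (camera adjusted p = 0.0592). The ligand gene Dll4 rose from 2.94 ± 0.525 CPM to 28.2 ± 2.32 and 30.7 ± 0.0639, the ligand gene Jag1 from 38.7 ± 4.69 to 140 ± 2.97 and 138 ± 3.4, and the targets Hes1 (1.52), Nrarp (1.58) and Hey1 (2.6, adjusted p = 3.5e-05) rose in both clones. Notch1, the receptor, had 71.1 ± 21.99 CPM in WT, 58.4 ± 6.83 in clone 1 (-0.29, adjusted p = 0.201) and 37.7 ± 1.48 in clone 2 (-0.92, adjusted p = 0.00111), and fell for the mean of both clones (-0.60, adjusted p = 0.00512). The call of Notch1 was lost without WT replicate 2 (-0.24, adjusted p = 0.123), and its change was -0.94 with chromosome shifts removed. For the mean, the list had a camera adjusted p of 0.0316, which became 0.0916 without WT replicate 1 and 0.0567 without clone 1 replicate 1, a median of 0.25 without WT replicate 2, and adjusted p = 0.366 with an estimated correlation.

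Of 27 Wnt pathway genes 12 fell and 7 rose for the mean of both clones, with identical counts adjusted over the list alone and a median of -0.38. The list was called in clone 1, with 13 lower, 8 higher and a median of -0.395 (camera adjusted p = 0.00665, and adjusted p = 0.455 with an estimated correlation), and not in clone 2, with 10 lower, 7 higher and a median of -0.173 (camera adjusted p = 0.0732). The secreted Wnt inhibitor Sfrp1 fell from 14.04 ± 0.230 CPM to 0.869 ± 0.170 and 0.153 ± 0.0334, the receptor gene Fzd1 from 23.4 ± 2.71 to 0.199 ± 0.155 and 0.805 ± 0.388, and the matricellular gene Ccn4 (-2.63) and the receptor gene Fzd7 (-2.61) fell too. For the mean, the list's camera adjusted p of 0.013 became 0.0535 without clone 1 replicate 1, 0.0838 without clone 1 replicate 2 and 0.0816 without a filter on low counts, its median was -0.206 with a filter of 1 CPM, and it was adjusted p = 0.402 with an estimated correlation. YAP and TAZ targets rose on balance, 10 of 24 higher and 5 lower, or 11 and 6 when adjusted over the list alone, with a median of 0.22 (camera adjusted p = 0.0168, and adjusted p = 0.366 with an estimated correlation). Areg rose from 6.43 ± 1.43 CPM to 58.9 ± 4.38 and 66.1 ± 3.45, and Ccn2 (1.56) and Dock5 (1.49) rose in both clones. Dlc1 fell from 2.43 ± 0.603 to 0.513 ± 0.228 and 0.0216 ± 0.0305 CPM, and Arhgef17, Wwtr1, Ptpn14 and Gadd45b fell as well.

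Genes of the TGF-beta and BMP pathway were not called as a list, with 16 of 34 higher, 10 lower and identical counts adjusted over the list alone (camera adjusted p = 0.0945, and 0.592 with an estimated correlation), although the list passed the threshold without WT replicate 2 (adjusted p = 0.0224). Its median of 0.21, which was 0.136 with upper-quartile scaling and 0.316 without WT replicate 2, and its mean of -0.24 differed in sign. Bmp7, a secreted ligand, had 13.9 ± 1.65 CPM in WT and no read in the clones, at least 402-fold lower. The latent TGF-beta binding genes Ltbp1 (1.88) and Ltbp2 (2.43) rose, and the co-receptor gene Tgfbr3 fell from 4.08 ± 0.328 CPM to 0 in clone 1 and 0.210 ± 0.130 in clone 2. Of 23 stem cell and aldehyde dehydrogenase genes 6 rose and 9 fell, with identical counts adjusted over the list alone (camera adjusted p = 0.628, and 0.691 with an estimated correlation). Procr, the protein C receptor, rose from 33.5 ± 3.07 to 98.4 ± 9.97 and 142 ± 11.3 CPM, and the proto-oncogene Myc from 85.1 ± 2.49 to 199 ± 14.9 and 232 ± 5.93 CPM. The mitochondrial folate enzyme gene Aldh1l2 had 9.43 ± 1.73 CPM in WT and 3 reads over both clones, a ratio of 258.7 with an interval of 87.51 to 1263.

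Of 51 Polycomb and heterochromatin factors 13 rose and 12 fell, with identical counts adjusted over the list alone (camera adjusted p = 0.466, and 0.592 with an estimated correlation), and the median of -0.00471 and the direction given by camera differed in sign. The Polycomb subunit genes Phc2, from 112 ± 19.9 CPM to 328 ± 9.54 and 324 ± 15.6, and Phc1 (0.96) rose, and the methylcytosine dioxygenase gene Tet2 (-1.34) fell. Its relative Tet1 had 2.68 ± 0.534 CPM in WT and 1 read over both clones, a ratio of 220 with an interval of 38.21 to 8811. Lists read as signs of RNA quality were not called in this comparison. Of 10 nuclear and structural RNAs, Snhg1 (1.49) and Snhg12 (1.16) rose, and Malat1 (-1.32), Rn7sk and Gas5 fell (camera adjusted p = 0.516, and 0.691 with an estimated correlation). Of 9 mitochondrially encoded genes mt-Nd6 fell, from 52.7 ± 16.8 CPM to 27.0 ± 3.43 and 34.0 ± 3.88 (camera adjusted p = 0.87, and 0.973 with an estimated correlation). In clone 1 its change of -0.96 was -0.59 without WT replicate 1. The medians of both lists turned with the WT library kept. That of the mitochondrial list was -0.40 with all libraries, -0.98 without WT replicate 2, where the list passed the threshold (adjusted p = 0.0388), and 0.825 without WT replicate 1 (adjusted p = 0.343), and that of the nuclear RNAs was 0.06, 0.355 (adjusted p = 0.151) and -0.18 (adjusted p = 0.822). Counts adjusted over the list alone were identical for both of these lists.

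**Figure D2:**
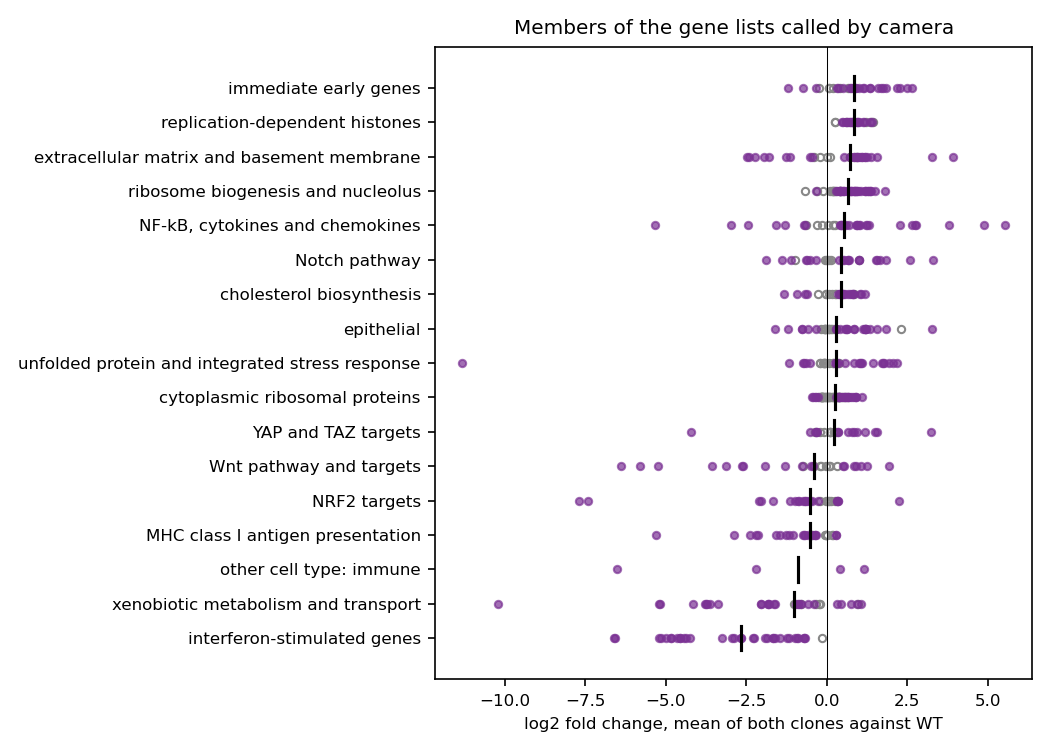
Log2 fold changes, mean of both clones against WT, of the members of the 17 gene lists called by camera. Each point is a gene, filled where it was called and open where it was not, and the black line is the list's median, which runs from -2.67 for the interferon-stimulated genes to 0.84 for the immediate early genes.

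Across the 31 lists, which were written before the data were examined, camera with its preset correlation called 17. With a correlation estimated for each list camera called 0, with 4 lists at an unadjusted p under 0.05, and fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, called 21. List calls by camera therefore hold only for the preset correlation. Fry alone called the TGF-beta (fry adjusted p = 0.041), hypoxia (0.041), p53 (0.0297), heat shock (0.0113) and fibroblast and endothelial (0.00701) lists. It did not call the matrix list (0.0932), which camera called. Where a list is described as called or not called, camera at its preset correlation is meant. Of the 17 lists, 9 were also called in each clone and 8 in 1 clone alone, and of those 8 the NF-kB and stress response lists also differed between the clones when these were compared directly. Among the list members named as higher or lower for the mean of both clones, Abcc1, Abcc4, Akr1b8, Uqcrc1, Cox4i1, Gadd45b, Gas5, Jun, Krt14, Psme3, Rpl22, Rpl23, Rplp1, Taf1b, Cd14 and Notch1 were called in clone 2 and not in clone 1, Arhgef17, Ptpn14, Rn7sk, Rps24, Slc6a9 and Tnfrsf9 in clone 1 and not in clone 2, and Pdia3 in neither.

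Clone 1 against WT asked what changed in that clone. Anxa8, a calcium-dependent membrane-binding annexin, fell from 36.1 ± 3.20 CPM in WT to 3.96 ± 0.119 in clone 1 (-3.18, SE 0.146, adjusted p = 3.35e-09) and had 38.2 ± 2.19 CPM in clone 2 (0.08 against WT, adjusted p = 0.608). The tumour suppressor gene St5 (-1.78), the axon guidance gene Ntn1 (-1.56) and the chondroitin sulfotransferase gene Chst11 (-1.55) also fell in clone 1 without a call in clone 2. The change of Ntn1 was -1.04 without WT replicate 2. The corepressor gene Tle4, from 9.77 ± 1.38 to 28.8 ± 1.01 CPM (1.57), and Adamtsl3 (1.41), the histone gene Hist2h2be (1.24) and the mitochondrial enzyme gene Fahd1 (1.19) rose in clone 1 and were not called in clone 2. The change of Fahd1 was 0.58 with chromosome shifts removed. A call between the clones was part of the rule that named these 8 genes, and its adjusted p-values ran from 1.23e-08 for Anxa8 to 0.00309 for Ntn1. Of all 1704 genes called in clone 1 and not in clone 2, 735 differed between the clones. In all, 6939 genes were called in clone 1, 3365 higher and 3574 lower, and 1087 and 1548 changed by more than 2-fold. With a required change of more than 1.5-fold, 2684 were called.

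Clone 2 against WT asked the same of the other clone. Cxcl5, a neutrophil-attracting chemokine, rose from 33.0 ± 4.76 CPM to 232 ± 2.63 (2.81, adjusted p = 3.45e-09) and had 29.5 ± 1.61 CPM in clone 1 (adjusted p = 0.294). The stromelysin Mmp3 rose from 11.6 ± 2.46 to 84.1 ± 6.83 CPM (2.84), and the ubiquitin ligase gene Neurl3 (2.15) and the actin-binding gene Aif1l (1.81) rose as well. Arfgef3 (-1.96), Afap1l2 (-1.67), the transcription factor gene Plag1 (-1.62) and Ankrd12 (-1.46) fell in clone 2 and were not called in clone 1. These 8 genes were named by the same rule, with adjusted p-values between the clones from 1.21e-08 for Cxcl5 to 8.81e-05 for Plag1. Of all 2068 genes called in clone 2 and not in clone 1, 899 differed between the clones. In all, 7303 genes were called in clone 2, 3463 higher and 3840 lower, and 1081 and 1772 changed by more than 2-fold. With a required change of more than 1.5-fold, 3032 were called.

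Most calls were common to the clones. In the same direction, 5166 genes were called in both, 2445 higher and 2721 lower, which were 74.4% of the calls of clone 1 and 70.7% of those of clone 2, and 69 genes were called in opposite directions. The cyclin gene Ccnd1, from 544 ± 12.4 CPM to 1942 ± 48.1 and 2204 ± 96.1, and the hyaluronan receptor gene Cd44, from 151 ± 18.3 to 432 ± 28.8 and 421 ± 47.0 CPM, rose in both and were singled out after their values were seen. More than 2-fold changes in both clones were found for 660 higher and 1244 lower genes. Independent lists of these sizes would share 847 higher and 998 lower genes. Both comparisons used the same WT libraries. In 20 simulations of unchanged groups against them, at most 2 genes were called in both, and the differences in log2 CPM of the clones from WT, with a prior count of 2, correlated across genes at a median of 0.565, against 0.879 in the data (Spearman 0.824). Their covariance was 1.08 against a simulated 0.0352. In a split chosen after the data were seen, each clone was compared with 1 WT library of its own. With WT replicate 1 for clone 1 and replicate 2 for clone 2, 4594 genes were called in both, with a correlation of 0.832 and a covariance of 1.05, and with the WT libraries exchanged 4149 genes were called in both, with 0.774 and 1.01. Since the split left 1 WT library to each comparison, part of the excess in the count of 5166 may come from the shared controls. With a required change of more than 1.5-fold, 1925 genes were called in both.

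**Figure D3:**
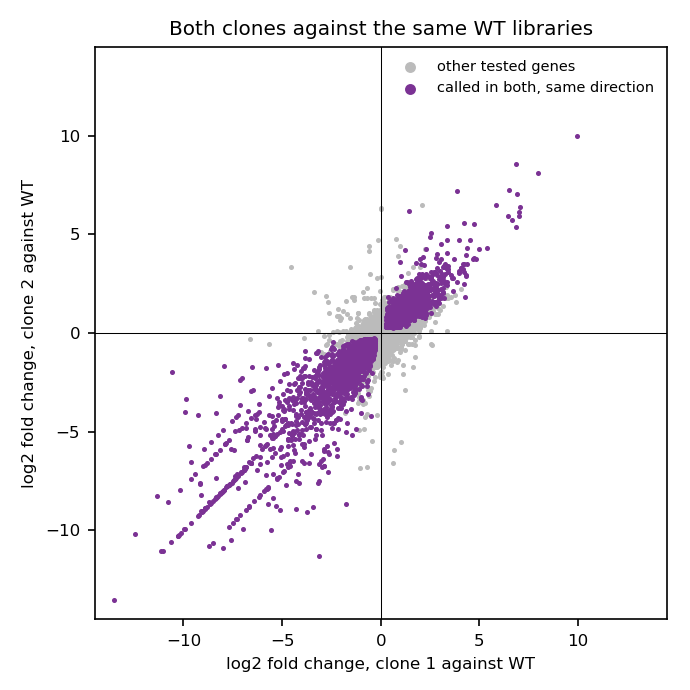
Fitted log2 fold changes of the 13755 tested genes in clone 1 (horizontal) and clone 2 (vertical) against the same WT libraries, with the 5166 genes called in both in the same direction in purple and all others in grey. Of the purple genes 2445 were higher and 2721 lower in both clones, and fitted values of genes with no reads in a clone depend on the prior count of the fit.

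Clone 2 against clone 1 asked whether the knockout clones differed from each other. The largest group difference was in cytokine and chemokine genes under NF-kB control. Il1a, interleukin 1 alpha, had 19.9 ± 2.48 CPM in clone 1 and 546 ± 8.83 in clone 2 (log2 difference 4.78, adjusted p = 2.26e-10). Csf3, granulocyte colony-stimulating factor, had 41.7 ± 0.233 and 331 ± 28.5 CPM (2.99), the chemokine gene Cxcl1 48.6 ± 6.95 and 293 ± 35 CPM (2.59), and Tnfaip2 308 ± 20.04 and 522 ± 18.5 CPM (0.76). Of 35 tested members of this list, 24 were higher in clone 2 and 1, the adhesion molecule gene Vcam1, was lower, with a median difference of 0.97, and adjusted over the list alone 26 were higher and 3 lower. The camera adjusted p was 8.91e-39, and adjusted p = 0.133 with an estimated correlation. Immune markers stayed low beside it, with Ptprc at 0.0445 and 0.102 CPM, while Cd14 had 7.48 and 20.9 CPM in clones 1 and 2. Against WT, as the mean of both clones, 22 members of the list rose and 7 fell, or 22 and 8 when adjusted over the list alone, with a median of 0.54 (camera adjusted p = 0.000584, and adjusted p = 0.366 with an estimated correlation). The list was called in clone 2, with 23 members higher, 6 lower and a median of 0.91 (camera adjusted p = 1.65e-11, and adjusted p = 0.217 with an estimated correlation), and not in clone 1, with 12 higher, 10 lower, a median of 0.16 and a mean of -0.034 (camera adjusted p = 0.631). The members that fell for the mean of both clones were Ccl2, Ccl5, Csf1, Tnfrsf9, Icam1, Vcam1 and Birc3.

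Further lists differed between the clones by smaller amounts. Xenobiotic genes were higher in clone 2, 11 higher and 4 lower of 33 (median 0.34, camera adjusted p = 0.022, and adjusted p = 0.707 with an estimated correlation), among them Mgst1 (2.17) and Aldh3a1 (2.71). Adjusted over the list alone, 14 were higher and 6 lower. Of 45 genes of oxidative phosphorylation 13 were higher and 1, Ndufv2, lower, or 15 and 1 when adjusted over the list alone (median 0.22, camera adjusted p = 0.00507, and adjusted p = 0.763 with an estimated correlation). Of 34 stress response genes 11 were higher and 1, Nupr1, lower, or 13 and 1 when adjusted over the list alone (median 0.23, camera adjusted p = 0.00754, and adjusted p = 0.425 with an estimated correlation). Nuclear RNAs were lower in clone 2, 6 of 10 with none higher and identical counts adjusted over the list alone (median -0.83, camera adjusted p = 0.00507, and adjusted p = 0.425 with an estimated correlation). This list was read as a sign of RNA quality. A difference in the RNA of the libraries can therefore not be told apart here from a difference between the clones. Malat1, an abundant nuclear non-coding RNA, had 3311 ± 199 CPM in WT, 1838 ± 152 in clone 1 and 953 ± 101 in clone 2, and Snhg1 had 101 ± 11.5, 398 ± 7.97 and 204 ± 9.85 CPM. In all, 3028 genes differed, 1550 higher and 1478 lower in clone 2, and 286 and 393 by more than 2-fold. This count depended on the libraries in the fit. It was 625 without clone 2 replicate 1, 985 without clone 1 replicate 2, 1208 without clone 1 replicate 1 and 1711 without clone 2 replicate 2, and rose to 4406 and 4445 without WT replicates 1 and 2 and to 4444 with the clones alone in the fit. With a required change of more than 1.5-fold it was 344.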

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

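The tests of other cell types and of shared descent were chosen after the results were seen, as was the fit with chromosome shifts removed.

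Genes read in WT and nearly unread in both clones formed the first pattern. With limits set after the data were seen, 66 genes had at least 3 CPM in both WT libraries and under 0.2 CPM in each clone. They included Hexa, Mal2, Vldlr, Ly6e and Bmp7. A gene counted as lost in 1 clone alone only if the other clone had at least 3 CPM in both libraries. By this rule 1 gene was lost in clone 1 alone (Fam111a, 44.3 CPM in WT, 0.022 in clone 1 and 11.4 in clone 2) and 0 in clone 2 alone. Genes between 0.2 and 3 CPM in the other clone, such as Tgfbr3, P4ha2, Fzd1 and Sfrp1, entered none of these counts. The low count of single-clone losses therefore depends on the limits. Deletions spanning neighbouring genes are argued against for most of the 66 genes, since 3.03% had another of them as the next gene read in WT and the highest of 1000 shuffles gave 12.12%. Immune, fibroblast or endothelial cells in the WT cultures are argued against too, because in none of 9 such cell types, with 48 markers in all, was the median marker in WT above 0.749% of the 6.59 CPM median of the lost genes (Lyz2, S100a8 and Cd3e had 0 CPM and Col1a1 0.217), though Pdgfra (39.3 CPM), Cd74 (26.6, and 0.466 and 0.175 in the clones) and Cd68 (12.9) were read in WT. Descent of both clones from one cell of a mixed culture and loss of Ki-67 in each clone cannot be told apart. Both predict more genes lost in both clones than in 1 alone, as the 66 against 1 by these limits showed, and either may hold.

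Chromosome-wide shifts formed the second pattern, with median log2 changes in clones 1 and 2 of 0.603 and 0.27 on chromosome 17, 0.297 and 0.433 on chromosome 8, and -0.394 and -0.286 on chromosome 10, and of opposite sign on 4 of 20 chromosomes, among them chromosome 14 (-0.204 and 0.162) and chromosome 4 (0.23 and -0.056). Chance is argued against, since the SD of the chromosome medians was 0.233 and 0.186 and the lower clone's was 3.38 times the highest of the shuffles. GC content and gene length are argued against as well, since 97.7% of the SD stayed in the lower clone without their trend. Medians of neighbouring windows correlated at 0.796 and 0.652 against at most 0.189 and 0.235 in shuffles, over 193 pairs. The windows were shuffled over all chromosomes, so differences between chromosomes alone raise this correlation, and it does not favour 1 source over another. Copy-number change of chromosomes or large segments stays open as a hypothesis without DNA data. No biological explanation from the design was tested for these shifts.

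Higher NF-kB and cytokine genes in clone 2 than in clone 1 formed the third pattern, with a median difference of 0.97. Immune cells in the clone 2 cultures are argued against, because in none of 6 immune cell types was the median marker in clone 2 above 0.431% of the median rise of 11.8 CPM, though Cd14 had 20.9 CPM. Chromosome-wide shifts are argued against by their size, since the largest median difference of a chromosome between the clones was 0.378, on chromosome 14. With shifts of this size, the 99.8% of the list's median difference that stayed after their removal adds little. As for a single clone 2 library, 82.9% of the members (29 of 35) had both clone 2 libraries above both clone 1 libraries. For these members the difference did not rest on a single clone 2 library. The list was singled out for its calls between these same libraries, so the 16.7% that chance gives is no measure here. A difference between the clones themselves stays open as a hypothesis, untested beyond these 2 clones. Library preparation stays open too, since reads left from ribosomal RNA were lower in both clone 2 libraries than in those of clone 1.

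Named genes whose change against WT differed between the clones by edgeR's test are given with the log2 difference, clone 2 minus clone 1. Among genes named in advance these were Mki67 (-1.02), Vim (-0.38), Cdh1 (-0.57), Epcam (-0.86), Mcm2 (0.34) and Notch1 (-0.63). Among the largest shared changes they were Mmp9 (2.10), Tnc (-0.89), Rgs16 (2.52), Il1a (4.78), L1cam (-1.13), Mmp10 (2.37), Lcp1 (1.55), Zfp704 (1.72) and Pmp22 (2.24). Genes called in 1 clone alone were Tle4 (-1.27), Adamtsl3 (-1.05), Hist2h2be (-1.65), Fahd1 (-0.88), Anxa8 (3.27), St5 (1.86), Ntn1 (1.46), Chst11 (1.42), Mmp3 (2.85), Cxcl5 (2.98), Neurl3 (2.16), Aif1l (1.61), Arfgef3 (-2.02), Afap1l2 (-1.53), Plag1 (-1.35) and Ankrd12 (-1.33).

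List members that differed and were higher in clone 2 were Ccne1 (0.87), Ung (0.49), Rrp9 (0.71), Sparc (1.23), Lama3 (0.65), Lamb3 (0.90), Csf3 (2.99), Cxcl1 (2.59), Tnfaip2 (0.76), Mgst1 (2.17), Gsta4 (0.98), Aldh3a1 (2.71), Osgin1 (0.62), Blvrb (0.52), Procr (0.53), Fzd1 (2.03), Ccn4 (0.53), Ccn2 (0.65), Dock5 (0.57), Ltbp2 (0.75), Uqcrq (0.37), Ier3 (0.66), Fosl1 (0.52), Dusp5 (0.81), Hspb8 (1.13) and Fkbp4 (0.33). Those lower in clone 2 were Uhrf1 (-0.45), Itga6 (-0.38), Oasl1 (-0.98), Ephx1 (-0.84), Sfrp1 (-2.48), Ltbp1 (-0.37), Trp53inp1 (-1.32), Dnajb4 (-0.73), Rps18 (-0.51), Rpl10a (-0.47), Snhg1 (-0.96), Malat1 (-0.95) and Snhg12 (-0.72). Fitted differences of Dlc1 (-4.04), Tgfbr3 (5.10) and P4ha2 (2.56) rest on 0 to 3 reads in a clone and depend on the prior count. Lists called between the clones by camera at its preset correlation are given with their median. They were the NF-kB (0.966), xenobiotic (0.338), oxidative phosphorylation (0.223), stress response (0.231) and nuclear RNA (-0.828) lists. None of them was called by camera with an estimated correlation (adjusted p = 0.133 to 0.763).

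Reads on the strand that was not counted were higher in the clones than in WT for 4 genes in a screen. The screen looked only for large rises called in both clones, among genes with most of their reads on that strand. Falls and smaller rises were not searched for. In clone 2, clone 1 and WT, Gm14486 had 0.258, 0.773 and 0 CPM on that strand, Anks6 1.03, 0.817 and 0.0297, Slc4a5 1.37, 1.15 and 0.144, and Ccdc184 0.618, 0.663 and 0.0479. Gm14023, with 109, 4.2 and 1.6 CPM, and Gm28513, with 36.6, 5.7 and 0.829, were noticed by eye and not tested. They overlap Il1a (546, 19.9 and 7.47 CPM) and Rgs16 (196, 34.2 and 5.82 CPM), which lie on that strand, so these values are not separate from those of the named genes.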

How the results depend on the processing

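The fit with chromosome shifts removed and the fit without mitochondrial and ribosomal RNA genes were chosen after the results were seen, as was the split of the WT libraries between the clones; the others were planned. With a minimum change of 1.5-fold, 2684 genes were called in clone 1, 3032 in clone 2, 2870 for the mean of both clones, 344 between the clones and 1925 in both clones, since that test asks for a larger change. Which direction held more of the calls depended on the setting. With upper-quartile scaling 43.13% of the calls in clone 1 were higher, 40.19% in clone 2 and 41.16% for the mean of both clones. Without a count filter these shares were 54.74%, 51.4% and 51.62%. Between the clones 44.14% of the calls were higher with upper-quartile scaling and 58.18% with DESeq2's Wald test. With an estimated correlation camera called 0 of the 31 lists, with 4 at an unadjusted p under 0.05, while fry called 21. Leaving out 1 library at a time gave 625 to 4445 genes between the clones. Fits without 1 clone library gave 625 to 1711, where that clone rests on a lone library, and fits without a WT library gave 4406 and 4445, close to the 4444 with the clones alone, where the spread between the WT libraries no longer enters.

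Of 156 named gene results, all 156 kept their direction and side of the threshold with DESeq2's size factors and Wald test, limma-voom, the legacy fit and unstranded counts, 155 without a count filter, 154 with upper-quartile scaling and with a filter of 1 CPM, 151 with chromosome shifts removed, 145 with the 1.5-fold minimum and 153 to 156 with 1 library left out. Of 31 lists, 31 did so by the sign of the median with DESeq2's size factors, 30 with unstranded counts and with chromosome shifts removed, 28 with upper-quartile scaling and with a filter of 1 CPM, 24 without a count filter, and 26 to 30 with 1 library left out. The fit without mitochondrial and ribosomal RNA genes gave no value for 1 list and 1 gene, and 29 lists and 155 genes were the same. Most of the named genes were chosen for large changes or small p-values in the main fit. Their shares therefore do not carry over to calls in general.

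The results that turned were not called in either fit, except H2-K1 (-0.43) and H2-D1 (-0.43) with chromosome shifts removed. These turned from just above 0 by construction, because both lie on chromosome 17 and its medians (0.603 and 0.27) were subtracted, and so did Ccnb1 (-0.041), by the medians of its own chromosome. Upper-quartile scaling moved the median of all genes by -0.072, and no rescaling moved it by more than 0.1. With it H2-K1 (-0.062), H2-D1 (-0.068) and the medians of the S phase (-0.011), hypoxia (-0.0395) and nuclear RNA (-0.012) lists, all within that distance of 0, turned to lower. Without a count filter the same genes' median moved by 0.0755, and Cdh1 (0.0136) and the Polycomb median (0.0655), within that distance of 0, turned to higher. For the others the cause was not tested. The medians of the mesenchymal (-0.41) and heat shock (0.0031) lists turned without a count filter, and H2-K1 (-0.0054) and H2-D1 (-0.011) with a filter of 1 CPM. The Polycomb median also turned with unstranded counts (0.0015) and without mitochondrial and ribosomal RNA genes (0.0056), and the hypoxia median with chromosome shifts removed (-0.033). With 1 library left out, H2-K1 ran from -0.20 to 0.27 and H2-D1 from -0.036 to 0.056, and the list medians ran from -0.038 to 0.088 for hypoxia, -0.012 to 0.060 for Polycomb, -0.98 to 0.825 for mitochondrial genes, -0.18 to 0.355 for nuclear RNAs and -0.80 to 0.19 for fibroblast and endothelial markers. Depth limits genes under the floor of 0.132 to 0.288 CPM.

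The replicate numbers were not treated as pairs. Deviations of same-numbered libraries from their group mean correlated at -0.459 for WT and clone 1, and at 0.0299 and 0.0118 for the other groups, over 9212 genes. WT replicate 1 thus tended to deviate like clone 1 replicate 2. A block by the number does not model this, and its source was not tested. With the number as a replicate block, 6566 genes were called in clone 1, 7028 in clone 2, 7389 for the mean, 2566 between the clones and 4890 in both, and no named gene or list changed its call.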

Other observations

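The tests by symbol family were chosen after the data were seen.

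Families of genes that share a symbol stem were tested with Fisher's exact test for calls in both clones, 264 tests over 132 families with Benjamini-Hochberg adjustment. Of 59 tested histone genes (Hist), 27 rose and 1 fell in both clones (adjusted p = 0.000167 for rises). Of 11 interferon-inducible Ifi genes, 8 fell and 0 rose (adjusted p = 0.0284), and of 13 small nucleolar RNA host genes (Snhg) 8 rose and 1 fell (adjusted p = 0.0477). Members of a family are not independent. Plac1, a placental gene, Tbcel and the phospholipase gene Plcd1 were nearly unread in WT and read in both clones, with 0.118, 0 and 0.0295 CPM in WT, 4.12, 6.55 and 5.29 CPM in clone 1, and 6.96, 6.70 and 5.72 CPM in clone 2. The chitinase-like gene Chil1 was read in clone 2 alone, at 9.37 CPM against 0.0886 in WT and 0.111 in clone 1.

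Reads left from ribosomal RNA differed between the libraries of WT and between those of clone 1, and were lower in both clone 2 libraries than in all others. A difference in how the libraries were prepared cannot be told apart from the clone. Clone 2 against clone 1, clone 2 against WT and the mean of both clones against WT carry that limit. Gm42418, which collects such reads, had 17200 and 58100 CPM in WT, 24200 and 11200 in clone 1, and 3650 and 4240 in clone 2. Lars2 had 845 and 3990, 1510 and 801, and 21.7 and 21.1 CPM, and the mitochondrial ribosomal RNA gene mt-Rnr2 had 150000 and 73800, 85100 and 106000, and 61700 and 45800 CPM.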
